A study of Caenorhabditis elegans with 8 samples.

How the data were processed

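Messenger RNA was sequenced from whole Caenorhabditis elegans hermaphrodites of the wild-type strain N2 in 8 libraries, 2 in each of 4 groups: water at 1 day, arsenite at 1 day, water at 5 days and arsenite at 5 days. Groups were taken from the source labels. The labels give 100 nM for both the arsenite and the water samples, and the dose was not used in any test. The labels record 1 and 5 days as the age of the worms. The descriptions of the 1-day samples also give 24 h, without saying what this time measures, and those of the 5-day samples give no time. No label states how long the worms were exposed, so age and length of exposure are not separated here. The library numbers in the titles run from 23 to 26 at 5 days and from 31 to 34 at 1 day, so a library batch and time cannot be told apart. Nothing in the labels says that the 2 libraries of a group came from separate cultures, so p-values measure only the spread between these samples, which may be technical.

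The deposited count table holds whole-number read counts for 46748 WormBase gene identifiers. Per the submitters' processing notes, the tools named are CASAVA 1.7, STAR 2.4.1d and featureCounts 1.4.6-p4 with the genome build WBcel235; the annotation release, the strand setting and the treatment of reads that map to several places are not given in the sources used here. Counts of near-identical gene copies, pseudogenes and genes that overlap on opposite strands are therefore uncertain. Per the labels' protocols, libraries were made with Illumina's kit for mRNA, without a stated strand protocol. All columns of both tables matched the title of 1 sample.

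A second deposited table holds RPKM values. In this table the ratio of the divisors of a pair of libraries took 12 values set by the row number modulo 12 in at least 99.96% of rows for 21 of the 28 pairs, within a tolerance of 0.1% and for rows with at least 100 counts in both libraries. For the other 7 pairs the ratio was 1 in at least 99.98% of rows and did not vary with the row number. The ratio matched that of the libraries' own totals in at most 8.654% of rows. RPKM values of different libraries were thus not on a common scale, and they served only for alternative tests.

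Gene names came from a reference table (43693 identifiers) and, for 9 mitochondrial genes, from overlap with RefSeq genes on the same build; 3046 identifiers without a symbol keep their identifier. Coordinates are from the WBcel235 annotation.

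Counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes were kept with filterByExpr by group (minimum count of 10, minimum total of 15), which left 14449 genes, and libraries were scaled by TMM. A quasi-likelihood test with robust estimation was fitted to 4 group means over all 8 libraries, so that the groups share 1 estimate of the spread. The contrasts were arsenite against water at 1 day, at 5 days and averaged over both times, the difference between the arsenite effects at 5 days and 1 day, and 5 days against 1 day in water and in arsenite. P-values were adjusted by the Benjamini-Hochberg method and called under 0.05. Standard errors were taken from the fold change and its F statistic. Intervals are 95% intervals. CPM values are TMM-normalized. Where a group had 10 or fewer counts of a gene given in the text, the ratio is given with its exact Poisson interval, which covers counting error only, and a group at 0 was set to 3 counts per library. For hsp-70 and hsp-16.2 at 1 day it is given beside the fitted value.

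The 30 gene lists and the rule for named genes were fixed before the data were examined. Named genes are the 8 with the largest rise and the 8 with the largest fall among those past the test, with a mean of at least 5 CPM in one group and no overlap between the groups' libraries; where none passed in a direction, the 3 with the smallest p, described as not passing; up to 4 members of each list with the smallest p; and 17 fixed genes in the arsenite contrasts (gst-4, gcs-1, sod-3, hsp-4, hsp-6, hsp-60, hsp-16.2, hsp-70, mtl-1, mtl-2, ftn-1, vit-2, vit-6, daf-16, skn-1, pmk-1 and aip-1). Of these 17 the text gives single values for the lowest, the highest and gst-4 and the others as a range, a choice made after the data and the alternatives were seen, because many values near 0 changed sign between alternatives. For the difference between the arsenite effects the rule was up to 5 genes in each direction, and none passed. Lists were tested with camera in limma 3.58.1 on voom values at a preset correlation of 0.01 between genes, adjusted over the lists of a contrast. Camera with an estimated correlation and fry were the alternatives. With an estimated correlation, camera also refers its statistic to the 4 residual degrees of freedom left by 8 libraries in 4 groups. It can therefore lose a call whatever the correlation between members. Not matched to the table were 9 symbols of DAF-16 class I genes, 4 of other immune effectors, 3 of cytosolic heat shock proteins, 2 each of metal response, mitochondrial unfolded protein response and intestine genes, and 1 each of DAF-16 class II genes and collagens.

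The gene test was run on simulated counts for the 14449 genes with 200 changed, 10 times for each of 4 comparisons and for each of 2 spreads. With dispersions on the fitted trend, false calls averaged 4.402% to 4.881% of calls. With the gene-wise dispersions estimated from these libraries they averaged 9.475% to 12.13%, above the nominal 5%, so the adjusted p of a single gene may be too small. For genes over 10 CPM and with gene-wise dispersions, 91.78% of 1.5-fold changes and 99.44% of 2-fold changes were recovered for arsenite at 5 days, and 92.31% and 99.43% at 1 day. Over genes of any level, 51.65% and 72.05% were recovered at 5 days. The simulations gave each gene the same dispersion at both ages and no deviation shared by neighbouring library numbers. Recovery may therefore be overstated at 5 days, where the libraries spread more, and its likeness between the ages is not a result. With no change simulated between arsenite and water, the test at 5 days made 0 calls with trended dispersions and between 2 and 9 with gene-wise dispersions. In a simulation of 30 lists of 40 genes chosen at random, with each gene drawn independently, camera called 5 of the 5 lists shifted by 1.2-fold and 0 of the other 25. It gives no rate of false calls for lists whose members vary together, and the estimated correlation between members reached 0.754 among the fixed lists at 5 days.

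Alternatives chosen before the data were examined were 3 other scalings, no low-count filter and a stricter filter, the Wald test of DESeq2 1.42.0, limma voom, a fit to only the groups compared, limma on log2(RPKM + 0.5) and log2(RPKM + 0.1), a 2-fold threshold, and leaving out each library. A fit with neighbouring library numbers as a term within each time was chosen after seeing the data. The first pass of the simulation used 1 run per comparison and gave a share of false calls above 5%, which led to the 10 runs and the pair of spreads given here. Plots were drawn with matplotlib 3.10.9.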

Results

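The libraries held between 21598326 and 27317490 counts each, and counts were found for 18766 to 19015 genes per library. Log2 CPM values of replicate libraries correlated at 0.99286 to 0.99471 across genes, and those of water and arsenite libraries of the same age at 0.99226 to 0.99484. Between ages the correlation was 0.93939 to 0.94117. Genes are not independent replicates. The counts of each replicate pair differed by more than sampling noise, with chi-square over degrees of freedom of 3.804 to 7.615, so no library was counted as a duplicate. The first principal component held 85.8% of the variance and separated the ages. The second, with 3.4%, separated the 5-day libraries numbered 23 and 24 from those numbered 25 and 26, each pair holding 1 water and 1 arsenite library. The common biological coefficient of variation was 4.492% within the 1-day libraries and 7.309% within the 5-day libraries. The gene test shared 1 spread between them (5.883% over all 8 libraries). By itself this can make p too large at 1 day and too small at 5 days. The difference of libraries 23 and 24 from 25 and 26 is part of the 5-day spread, however. It falls on water and arsenite alike, which acts to make p of the arsenite contrast at 5 days too large. How these balance was not tested.

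**Figure D1:**
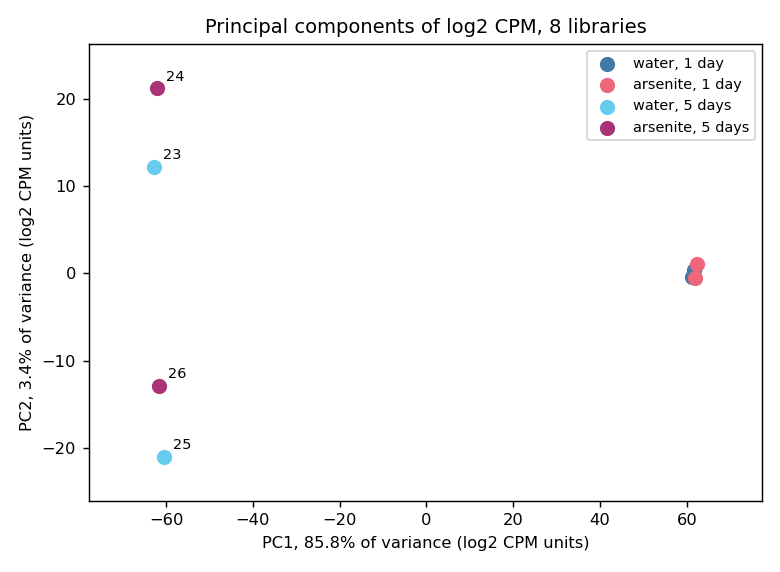
First and second principal components of log2 CPM for the 8 libraries, with 1 point per library, colour for the group and the title library number beside the 5-day points. PC1 (85.8% of variance) parts 1 day from 5 days, and PC2 (3.4%) parts libraries 23 and 24 from 25 and 26.

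The first comparison asked which messages differed between arsenite and water at 1 day. None of the 14449 genes passed the edgeR quasi-likelihood test. Cytosolic ribosomal protein genes had a median log2 fold change of -0.04, with 0 of 78 members past the test. The 3 genes of smallest p on the higher side, none of them passing, were the pseudogene WBGene00004677 (log2 fold change 0.34, SE 0.10), F31F6.1 (0.36, SE 0.13) and Y43C5A.3 (0.40, SE 0.15). On the lower side they were athp-3 (-0.56, SE 0.16), W03C9.5 (-0.45, SE 0.14) and cox-6C (-0.32, SE 0.10), a subunit of cytochrome c oxidase.

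Genes used as reporters of stress gave no call at 1 day. The 17 fixed genes had log2 fold changes between -1.04 for hsp-70, a heat-inducible chaperone, and 0.52 for hsp-16.2, a small heat shock protein, and both 95% intervals included 0 (-2.39 to 0.31 and -1.09 to 2.12). Both values rest on few counts. For hsp-70 there were 15 and 5 counts in water and 2 and 8 in arsenite, a ratio of water to arsenite of 2.074 (0.9267 to 4.962 from counting error alone). For hsp-16.2 there were 3 and 3 in water and 7 and 2 in arsenite, a ratio of arsenite to water of 1.446 (0.4597 to 4.938). The glutathione S-transferase gene gst-4, a common reporter of SKN-1 activity, stood at 23.38 ± 1.185 CPM (SD, n = 2) in water and 24.76 ± 2.065 CPM in arsenite, a log2 fold change of 0.08 with an interval of -0.17 to 0.33. DESeq2 and limma voom also called 0 genes at 1 day, and 238 genes had an unadjusted p under 0.05 where 722.4 would be expected by chance. The shared spread lies above that within the 1-day libraries, so this deficit is not read as a sign of no effect. An edgeR fit to the 1-day libraries alone also called 0 genes, with a smallest adjusted p of 0.1002. Camera called the ribosomal protein list lower (adjusted p = 3.388e-05, against at least 0.7348 with an estimated correlation for every list), and without replicate 2 of water at 1 day the list was called in the opposite direction, while without replicate 2 of arsenite at 1 day its direction also turned. Lists called numbered 2 to 7 on leaving out any 1 of the 8 libraries, and 1 gene, WBGene00004677, was called without replicate 1 of water at 5 days. Nuclear ribosomal RNA took 2.6 ± 0.5933% of counts in water and 3.224 ± 0.3062% in arsenite (SD, n = 2).

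**Figure D2:**
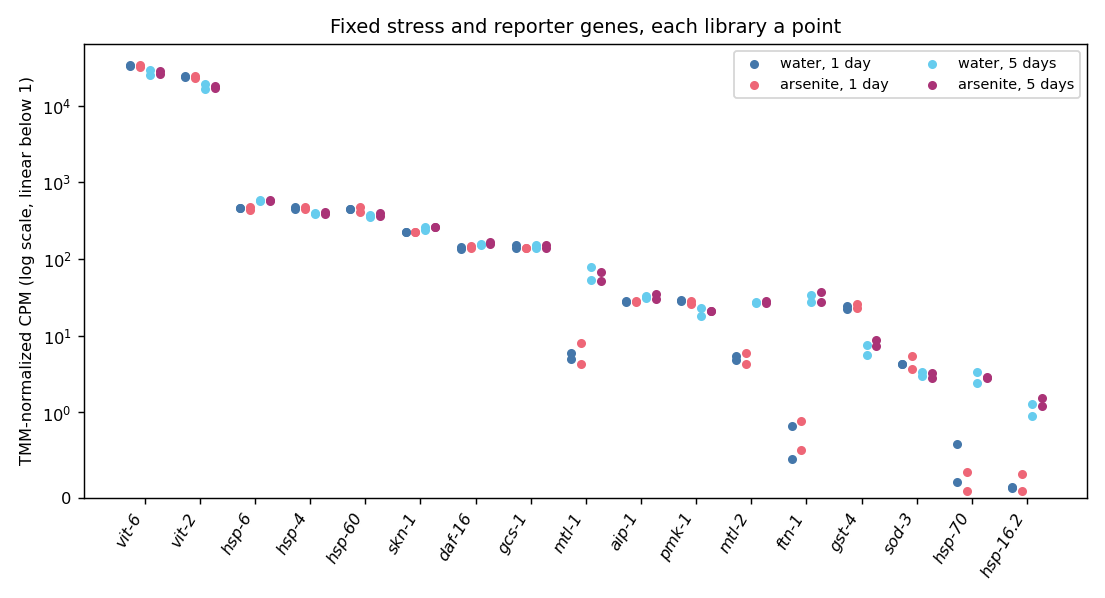
TMM-normalized CPM of the 17 fixed genes in each of the 8 libraries, with 1 point per library and colour for the group, on a log scale that is linear below 1. Mean levels of gst-4 at 1 day were 23.38 CPM in water and 24.76 CPM in arsenite, points under 1 CPM scatter widely, and the ages stand apart for genes such as ftn-1 and mtl-2.

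At 5 days arsenite and water differed in 2 genes, both higher in arsenite. The gene ncl-1, which encodes a B-box protein known as a repressor of nucleolar size, stood at 110.5 ± 6.493 CPM in water and 149.7 ± 0.03447 CPM in arsenite (SD, n = 2), a log2 fold change of 0.44 (SE 0.06, edgeR adjusted p = 0.004667). It lies on chromosome III from 7719729 to 7738105. WBGene00014294, annotated as a pseudogene on chromosome X from 13042182 to 13046220, rose from 20.17 ± 0.8832 to 31.01 ± 2.163 CPM (SD, n = 2), a log2 fold change of 0.62 (SE 0.11, edgeR adjusted p = 0.04164). Its reads may be shared with related sequence. Both genes were higher in 2 of 2 arsenite libraries than in either water library, which the rule for named genes requires. Such a lack of overlap, in either direction, held for 4267 of the 14449 genes (29.53%). No gene was called lower, and the 3 of smallest p on that side were ttr-15 (-0.26, SE 0.06), F29B9.11 (-0.29, SE 0.08) and tsp-8 (-0.55, SE 0.15).

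The 17 fixed genes at 5 days ran from -0.12 for the metallothionein gene mtl-1 (interval -0.96 to 0.71) to 0.31 for hsp-16.2 (interval -0.41 to 1.03), and none passed. The gene gst-4 stood at 6.601 ± 1.452 CPM in water and 8.06 ± 1.149 CPM in arsenite (SD, n = 2), a log2 fold change of 0.29 with an interval of -0.03 to 0.61. Camera called 7 lists at 5 days, and 0 held with an estimated correlation (adjusted p of at least 0.7383) or by fry (at least 0.7696). No member of any list passed over all genes, and 1, col-49, passed when adjusted over the list alone. Without replicate 2 of arsenite at 5 days 13 lists were called. Among the mitochondrial DNA-encoded subunits, 12 of 12 members had positive fold changes, such as COX2 (0.24, SE 0.08) and ND5 (0.71, SE 0.19). In the cuticle collagen list 12 of 133 were positive, and col-49 had -1.52 (SE 0.33) and col-149 -0.73 (SE 0.21). Positive members were 6 of 78 for ribosomal proteins, 5 of 36 for nuclear-encoded respiratory chain subunits, 4 of 23 for muscle genes, 10 of 37 for neuronal genes and 5 of 6 for vitellogenins. Examples were rpl-25.1 at -0.27 (SE 0.08), mlc-1, a myosin light chain, at -0.27 (SE 0.09), and mec-7, a tubulin of touch neurons, at -0.41 (SE 0.13). Libraries 23 and 24, of which 1 is from water and 1 from arsenite, differed from 25 and 26 in 5 of these 7 lists, by camera at the preset correlation in a fit with neighbouring library numbers as a term. Collagens (10 members higher and 34 lower, adjusted p = 3.301e-12; 0.6985 with an estimated correlation), muscle, ribosomal protein and neuronal genes were lower in 23 and 24, and mitochondrial DNA-encoded subunits higher (0.0001614; 0.6985), the same directions as in arsenite. The lists of nuclear-encoded respiratory chain subunits (0.05794) and vitellogenins (0.05688) were not called there, though their directions in 23 and 24, lower and higher, were again those in arsenite. With an estimated correlation the muscle (adjusted p = 0.6704), ribosomal protein (0.7415) and neuronal (0.6704) calls of this fit were lost too.

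An unadjusted p under 0.05 in the edgeR test was found for 573 genes, where 722.4 would be expected by chance. The shared spread lies below that within the 5-day libraries, so sharing it would not give this deficit. The deficit is not read as a sign of no effect. DESeq2 called 3 genes and limma voom 2. In simulated libraries with no arsenite effect the same test called 2 to 9 genes at 5 days with gene-wise dispersions and 0 with trended dispersions, and the simulations held no deviation shared by neighbouring library numbers. The count was 11 without replicate 1 of water at 5 days, 0 without either arsenite library at 5 days, 1 without either arsenite library at 1 day, 0 in a fit to the 5-day libraries alone, and 22 with neighbouring library numbers as a term, chosen after seeing the data, where ttr-15 (adjusted p = 0.03966), ND5 (0.01386) and col-49 (0.03706) also passed. Without replicate 1 or 2 of arsenite at 5 days, ncl-1 kept a log2 fold change of 0.43 with an adjusted p of 0.1684 and 0.1016, in a range over the alternatives of 2.183e-07 to 1, and WBGene00014294 had 0.54 and 0.68 with 0.9993 and 0.1016, in a range of 4.784e-06 to 0.9993. WBGene00014294 also lost its call without water replicate 1 (log2 fold change 0.57, adjusted p = 0.09717) or 2 (0.66, 0.07444) at 5 days and arsenite replicate 1 (0.62, 0.09098) or 2 (0.62, 0.08398) at 1 day, with a fold change close to the 0.62 of all libraries. Nuclear ribosomal RNA took 1.114 ± 0.1252% of counts in water and 1.684 ± 0.1379% in arsenite (SD, n = 2).

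Averaged over both times, no gene passed the edgeR test between arsenite and water. The smallest p belonged to ncl-1, with a log2 fold change of 0.23 (SE 0.04), and to WBGene00004677, a pseudogene on chromosome I from 15060299 to 15061150, with 0.53 (SE 0.07, adjusted p = 0.227). The latter was called by DESeq2 (adjusted p = 2.211e-09) and by limma voom (0.005396), which called 1 gene each, and its adjusted p ranged from 2.98e-25 to 1 over the alternatives. Its level was 166.7 ± 15.12 CPM in water and 210.9 ± 4.156 CPM in arsenite at 1 day, and 50.35 ± 9.141 and 82.69 ± 2.983 CPM at 5 days (SD, n = 2). Nuclear ribosomal RNA also took a larger share of counts in arsenite than in the water library numbered just before it in 4 of 4 pairs (3.44% against 3.019% and 3.007% against 2.18% at 1 day, 1.781% against 1.025% and 1.586% against 1.202% at 5 days). The labels give no such pairing, and at 1 day the groups overlapped (3.007% in 1 arsenite and 3.019% in 1 water library). The level of WBGene00004677 ran in the same order over the 4 groups as this share (means of 2.6%, 3.224%, 1.114% and 1.684%, groups ordered as for its level). Whether its change is separate from that of ribosomal RNA was not tested. With neighbouring library numbers as a term, chosen after seeing the data, 6 genes were called, among them ncl-1 (adjusted p = 0.006449) and WBGene00004677 (0.001688). The gene ints-3 followed at 0.16 (SE 0.04), and on the lower side cox-6C at -0.26 (SE 0.07), F23F1.10 at -0.36 (SE 0.10) and E01G4.6 at -0.53 (SE 0.14). The 17 fixed genes ran from -0.52 for hsp-70 to 0.41 for hsp-16.2, both with the few counts given above at 1 day, and gst-4 stood at 0.19 (interval -0.01 to 0.39). There were 412 genes with an unadjusted p under 0.05, where 722.4 would be expected by chance. Camera called 5 lists (mitochondrial DNA-encoded subunits with positive values, and nuclear-encoded respiratory chain, ribosomal protein, collagen and muscle genes with negative values). None held with an estimated correlation (adjusted p of at least 0.8179), and 3 members, cox-6C, sdhd-1 and col-49, passed when adjusted over the list alone. The mitochondrial DNA-encoded subunits moved in opposite directions at the 2 times. Positive members were 1 of 12 at 1 day (median log2 fold change -0.114) and 12 of 12 at 5 days (0.283). Muscle genes had 11 of 23 positive at 1 day (median -0.002) and 4 of 23 at 5 days (-0.127). The other called lists had negative medians at both times. Without replicate 1 of water at 5 days, 5 genes were called, and without replicate 2 there were 2. Lists called were 9 without replicate 1 of water at 5 days, 12 without replicate 2 of arsenite at 5 days, 2 without replicate 2 of water at 1 day and 8 without replicate 2 of arsenite at 1 day.

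The arsenite effect was next compared between the times. No gene passed the test of the difference, and 368 had an unadjusted p under 0.05, where 722.4 would be expected by chance. DESeq2 and limma voom also called 0. Across the 14449 genes the log2 fold changes at 1 and 5 days correlated at 0.004968 (Spearman 0.02296), and across the 7462 genes over 10 CPM at 0.07603. The effects shared 0 called genes, since 0 were called at 1 day. Without replicate 2 of water at 1 day the difference had 2 calls, and without replicate 1 of water at 5 days it had 1.

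In water, 8685 genes (60.11% of those tested) differed between 5 days and 1 day by the edgeR test, 4348 higher and 4337 lower at 5 days, and 3310 of them by more than 2-fold. Among the largest rises was ins-19, an insulin-like peptide gene with 0 counts in both 1-day water libraries and 195 and 97 at 5 days, at least 51.42-fold higher. T26H5.9 went from 5 counts over both libraries to 2720 and 2518, a ratio of 1116 (95% counting interval 478 to 3439). The neuropeptide-like gene nlp-39 had a ratio of 103.7 (47.36 to 283.7) and C50F7.5 one of 112.9 (57.05 to 262.4). The noncoding RNA tts-1 rose from 3.836 ± 0.2822 to 481.7 ± 61.65 CPM (SD, n = 2), and dod-3 rose by 6.14 (SE 0.30) on the log2 scale. T22B7.7 rose by 6.21 (SE 0.49) on the log2 scale. F46C5.1 had a ratio of 79.31 (41.53 to 174.2), and lost its call without either 1-day water library (adjusted p = 0.06078 and 0.06096, in a range over the alternatives of 5.826e-85 to 0.06096).

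The largest falls were mostly in collagens of the cuticle. The gene col-20 fell from 602.3 ± 61.53 to 2.646 ± 0.4417 CPM and col-129 from 158.4 ± 12.46 to 1.036 ± 0.009101 CPM (SD, n = 2). The genes col-81, col-139, col-124 and col-179 fell, with log2 fold changes of -6.44, -6.07, -5.76 and -5.51. The acyl-CoA dehydrogenase gene acdh-2 fell from 101.4 ± 2.034 to 1.941 ± 0.3795 CPM, and sri-40, a chemoreceptor-class gene, fell by 5.39 on the log2 scale. The collagen list moved both ways, with 51 of 133 members higher and 58 lower, and was called lower (camera adjusted p = 0.0385; 0.8002 with an estimated correlation).

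Most muscle and intestine genes on the lists fell. Of 23 muscle genes, 21 fell and 1 rose (camera adjusted p = 3.478e-13; 0.2171 with an estimated correlation), among them the myosin heavy chain unc-54, from 2383 ± 55.35 to 648.3 ± 61.29 CPM, and the troponin tnt-2, from 498.0 ± 0.3963 to 90.67 ± 8.396 CPM (SD, n = 2). Of 24 intestine genes, 21 fell and 2 rose (adjusted p = 2.26e-08; 0.2171 with an estimated correlation), with vha-6, a subunit of the proton pump, down by 2.03 (SE 0.06) and the acid phosphatase pho-1 down by 2.31 (SE 0.10) on the log2 scale. Vitellogenins, the yolk proteins made in the intestine, fell in 5 of 6 members (adjusted p = 0.004415; 0.2171 with an estimated correlation). The gene vit-1 fell from 4951 ± 7.774 to 483.1 ± 1.87 CPM (SD, n = 2), whereas vit-5 rose by 0.38 (SE 0.08). Together the 6 genes took 7.828 ± 0.06576% of counts in water at 1 day and 6.457 ± 0.3154% at 5 days (SD, n = 2).

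Reproductive lists moved apart. Sperm genes fell in 30 of 39 members and rose in 2 (adjusted p = 8.629e-06; 0.2171 with an estimated correlation), and the major sperm protein gene msp-19 was 30.03-fold lower (9.974 to 148.2). The msp genes are near-identical copies, so their counts are uncertain. Zygotic embryonic genes fell in 18 of 25 members and rose in 2 (adjusted p = 0.0002047; 0.2171 with an estimated correlation), with log2 fold changes of -1.83 for pha-4 and -1.89 for unc-120. Oocyte and early embryo genes rose in 16 of 33 and fell in 5 (adjusted p = 0.01573; 0.6114 with an estimated correlation), with perm-2 at 1.42 (SE 0.06). Germ line genes rose in 20 of 39 and fell in 7 (adjusted p = 0.0385; 0.7328 with an estimated correlation), with prg-1 at 0.53 (SE 0.06). Histones rose in 11 of 24 and fell in 2 (adjusted p = 0.02027; 0.6422 with an estimated correlation).

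Lists of detoxification genes differed in their result. UDP-glucuronosyltransferases fell in 38 of 62 members and rose in 9 (adjusted p = 9.225e-06; 0.1099 with an estimated correlation), and ugt-22 fell from 181.8 ± 3.23 to 40.47 ± 4.538 CPM (SD, n = 2). Phase II genes regulated by SKN-1 fell in 11 of 17 and rose in 2 (adjusted p = 0.01491; 0.2171 with an estimated correlation). Among them gst-4 fell by 1.82 (SE 0.14) and gst-13 by 1.60 (SE 0.12) on the log2 scale. ABC transporters fell in 23 of 46 and rose in 8 (adjusted p = 0.01596; 0.5659 with an estimated correlation). HIF-1 and hydrogen sulfide genes fell in 8 of 13 and rose in 0 (adjusted p = 0.001248; 0.2171 with an estimated correlation), with the cystathionine gamma-lyase cth-2 at 206.3 ± 6.789 CPM at 1 day and 71.95 ± 8.599 CPM at 5 days (SD, n = 2). Fatty acid metabolism genes fell in 20 of 36 and rose in 10 (adjusted p = 0.01573; 0.5659 with an estimated correlation), with log2 fold changes of -1.85 for acdh-1 and 1.78 for fat-2, a desaturase. Glutathione S-transferases (9 of 41 higher, 18 lower) and cytochromes P450 (19 of 64 higher, 22 lower) were not called as lists.

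Of the pair of immune lists, 1 was called. Other immune effectors rose in 33 of 61 members and fell in 12 (adjusted p = 0.01409; 0.6114 with an estimated correlation), including the antimicrobial peptide genes abf-2, from 0.2862 ± 0.1933 to 14.36 ± 1.744 CPM (SD, n = 2), and spp-1 by 2.72 (SE 0.13) on the log2 scale. C-type lectins and lysozymes moved both ways (47 of 122 higher, 37 lower) and were not called, yet lys-7, a lysozyme, rose from 75.02 ± 2.398 to 1260 ± 100.1 CPM. DAF-16 class II genes rose in 7 of 13 and fell in 2 (adjusted p = 0.0288; 0.2882 with an estimated correlation), led by dod-23 at 2.88 (SE 0.07). Cytosolic ribosomal proteins rose in 43 of 78 and fell in 9 (adjusted p = 9.225e-06; 0.7278 with an estimated correlation), with rpl-29 from 37.18 ± 2.377 to 172.3 ± 9.693 CPM (SD, n = 2).

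Metal and stress lists were not called, although single members changed. Of 17 metal response genes 8 rose and 3 fell, with log2 fold changes of 5.57 (SE 0.26) for the ferritin gene ftn-1, 2.39 (SE 0.13) for mtl-2 and -3.34 (SE 0.23) for cdr-1. Cytosolic heat shock proteins rose in 7 of 18 and fell in 6, and hsp-16.41 had a ratio of 43.15 (11.57 to 362.4). Antioxidant enzymes rose in 8 of 29 and fell in 7, the mitochondrial unfolded protein response in 5 of 18 and 9, the endoplasmic reticulum response in 7 of 21 and 10, and DAF-16 class I genes in 7 of 17 and 4. Nuclear-encoded respiratory chain subunits rose in 15 of 36 and fell in 11, mitochondrial DNA-encoded subunits in 1 of 12 and 3, proteasome subunits in 11 of 33 and 7, and neuronal genes in 9 of 37 and 8. Camera called 17 of the 30 lists, 0 with an estimated correlation, and fry called 23. With each list adjusted over the list alone, 375 members were higher and 437 lower, against 371 and 435 over all genes. Nuclear ribosomal RNA took 2.6% of counts in water at 1 day and 1.114% at 5 days. Chromosome X took 10.95% to 11.13% in the 1-day libraries and 8.981% to 9.052% in the 5-day libraries, and a library batch cannot be told apart from time.

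**Figure D3:**
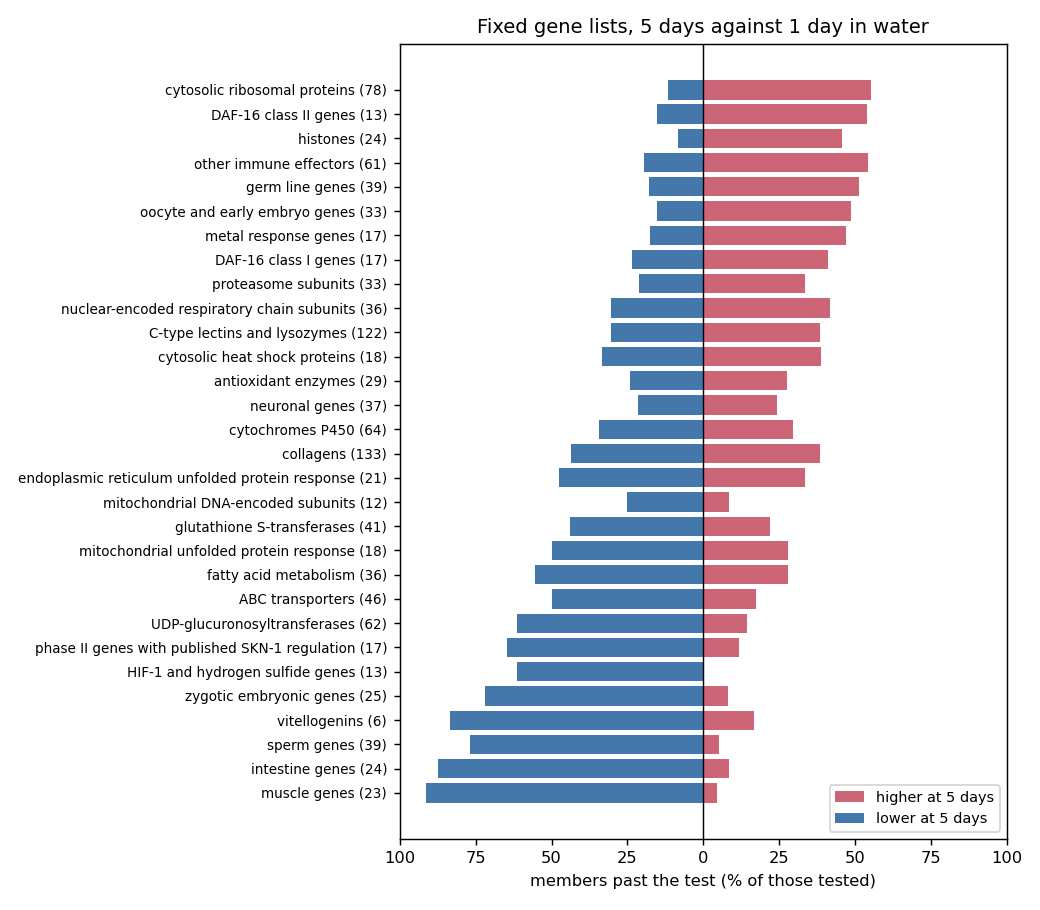
Share of tested members of each fixed list that were higher (right, red) or lower (left, blue) at 5 days than at 1 day in water by the edgeR test, in percent, with the number of members tested in brackets. Muscle genes (21 of 23 lower) and intestine genes (21 of 24 lower) lie at the bottom, and ribosomal proteins (43 of 78 higher) at the top.

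In arsenite, 8616 genes differed between 5 days and 1 day, 4371 higher and 4245 lower, and 3328 by more than 2-fold. The largest rises were again T26H5.9, with a ratio of 1295 (counting interval 505.6 to 4756), tts-1 and T22B7.7 at 7.05 and 5.86 on the log2 scale, nlp-39 with a ratio of 535.4 (95.64 to 21190) and ins-19 with 169.1 (46.42 to 1403). The defensin-like gene abf-2 had a ratio of 155.5 (66.3 to 480.3), the collagen col-41 one of 90.41 (43.59 to 225.9), and sysm-1 rose by 5.95 (SE 0.39) on the log2 scale. The largest falls were col-20, col-129, col-139, col-81 and col-124, with log2 fold changes of -8.28, -7.33, -6.73, -6.70 and -6.22, then acdh-2 at -5.85 and col-179 at -5.82. R09E10.6 was 67.85-fold lower (26.23 to 250.6).

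The gene lists gave similar counts in arsenite, where muscle genes fell in 20 of 23 members, intestine genes in 21 of 24, sperm genes in 29 of 39 and UDP-glucuronosyltransferases in 39 of 62, while other immune effectors rose in 33 of 61. Camera called 19 lists, 0 with an estimated correlation (adjusted p of at least 0.09767). Glutathione S-transferases (19 of 41 lower) and metal response genes (10 of 17 higher) were called in arsenite (adjusted p = 0.04348 and 0.03648; both 0.4407 with an estimated correlation) and not in water, but neither list passed the test of the difference. Across genes the time effects in water and in arsenite, which share no library, correlated at 0.9299. Both calls were higher for 3784 genes, where independent lists would share 1315, and both lower for 3781, where independent lists would share 1274. For 2 genes the calls were opposite, F53H2.4 and WBGene00014294, named after their values were seen, and neither passed the test of the difference.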

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

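For 6 gene lists the arsenite effect at 5 days differed from that at 1 day by camera at the preset correlation, and for 0 of them with an estimated correlation (adjusted p of at least 0.8757) or by fry (at least 0.9541). Lists called were 10 without replicate 1 of water or replicate 2 of arsenite at 5 days, 2 without replicate 1 of arsenite at 5 days, 1 without replicate 2 of water at 5 days and 3 without replicate 1 of water at 1 day. The median log2 difference, 5 days minus 1 day, was 0.357 for mitochondrial DNA-encoded subunits, -0.039 for cytosolic ribosomal proteins and 0.15 for vitellogenins. It was -0.178 for collagens, where 1 of 133 members had a group at 0 counts, -0.107 for muscle genes and -0.134 for neuronal genes.

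The lists called for arsenite at 5 days were weighed with a test whose prediction was written before its result was seen. Splitting the 4 libraries at 5 days the other possible ways, by neighbouring numbers or crosswise, called 13 and 4 lists, against 7 for arsenite against water. Of these 7, the split by neighbouring numbers also called 5 (mitochondrial DNA-encoded subunits, ribosomal proteins, collagens, muscle and neuronal genes), and the crosswise split called collagens and muscle genes. Only nuclear-encoded respiratory chain subunits and vitellogenins were called by the arsenite split alone. In the fit with neighbouring library numbers as a term, these lists also moved in the arsenite direction in 23 and 24, just short of a camera call (adjusted p = 0.05794 and 0.05688). The split by neighbouring numbers, 23 and 24 against 25 and 26, called 371 genes, against 2 for arsenite, which points to a structure of the samples. The prediction, another split with at least as many lists, was met by that split alone, since the crosswise split called 4 lists and 0 genes, fewer than arsenite. Whether lists of genes that vary together between any libraries account for the 7 calls is therefore left open, as is an effect of arsenite, and with 3 splits no share can fall under 0.05.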

How the results depend on the processing

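No paired analysis was possible by replicate number, because the labels give the libraries no replicate number that the groups share. A fit that pairs neighbouring library numbers was run instead, chosen after seeing the data. Leaving out a library leaves 1 in its group, which is assumed to vary like the others. The cause of a change was not tested, and a clause beside a count names only how that setting differs. A fit to only the groups compared uses fewer libraries and also estimates the spread from those groups alone, and these differences were not separated. Depth limits genes under 10 CPM, where fewer simulated changes were recovered.

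For arsenite at 1 day the main count of 0 became 2 with no low-count filter, 9 and 20 with limma on RPKM plus 0.5 and plus 0.1, and 0 to 1 on leaving out a library. At 5 days the count of 2 became 1 with upper-quartile factors, 14 without a filter, 1 with the stricter filter, which tests fewer genes, 7 and 9 on RPKM, 0 with only the groups compared, which uses fewer libraries, 0 with a 2-fold threshold, 22 with neighbouring numbers and 0 to 11 on leaving out a library. Averaged, 0 became 7 without a filter, 1 with DESeq2, 1 with limma voom, 1 and 10 on RPKM, 6 with neighbouring numbers and 0 to 5 on leaving out a library. For the difference, 0 became 1 without a filter, 14 on RPKM plus 0.1 and 0 to 2 on leaving out a library. RPKM values were not on a common scale between libraries.

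Between 1 and 5 days in water, 8685 became 5656 and 5620 on RPKM, 3310 with a 2-fold threshold and 7389 to 8869 on leaving out a library, and in arsenite 8616 became 3328 with a 2-fold threshold and 7168 to 8948. In arsenite the share of higher calls was 50.73%, against 36.76% and 36.81% on RPKM, where the median of all genes moved by -0.148 and -0.157. With neighbouring numbers 8672 and 8602 genes kept their call and direction.

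Lists called fell to 0 with an estimated correlation in all 6 contrasts and to 0 by fry in the 4 arsenite contrasts. Between times in water, calls were lost even for UDP-glucuronosyltransferases and for HIF-1 and hydrogen sulfide genes. Their estimated correlations (-0.003 and -0.025) lay below the preset 0.01. A call lost in this way does not by itself show that the members of a list vary together. At 1 day the 1 list became 5 with the stricter filter and 2 to 7 on leaving out a library. The 7 lists at 5 days became 7 to 13, the 5 averaged 2 to 12, and the 6 for the difference 1 to 10. Between times, 17 lists in water became 11 with the stricter filter and 15 to 17 on leaving out a library, and 19 in arsenite became 12 and 16 to 19. The correlation of the arsenite effects, 0.004968, was -0.1025 on RPKM plus 0.5, and -0.003971 to 0.02796 on leaving out a library.

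Of the 17 fixed genes, 16 changed sign in at least 1 alternative at 1 day, 13 at 5 days and 15 averaged, and none was called in any. On leaving out a library at 1 day, hsp-70 ranged from -2.28 to 0.03, hsp-16.2 from -0.63 to 1.16 and gst-4 from -0.01 to 0.16; averaged, hsp-70 ranged from -1.13 to 0.02 and hsp-16.2 from -0.16 to 0.74. The sign turned without replicate 1 of water at 1 day for hsp-70 and replicate 1 of arsenite at 1 day for hsp-16.2 and gst-4. At 5 days mtl-1 ranged from -0.38 to 0.17, and turned without replicate 1 of water (0.17) or replicate 2 of arsenite (0.05). WBGene00014294 lost its call in 12 alternatives and ncl-1 in 5, not counting the 2-fold threshold, which neither reached. Of the genes named between times, 114 in water and 116 in arsenite kept their call in every alternative run on single genes, which leaves out the 2-fold threshold; the others lost it in at least 1, in 36 and 26 cases, and 0 changed direction.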

Other observations

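Gene families, grouped by symbol prefix after the data were seen and after members of the fixed lists were left out, also differed between 1 and 5 days in water. Of 89 families with at least 12 tested members, the proton pump subunits (vha) had 18 of 19 members lower and 0 higher (Fisher's exact test against all other genes, one-sided, adjusted p = 9.246e-07 over 178 tests), and the same counts held in arsenite. F-box B genes (fbxb) had 54 of 94 lower and 5 higher (adjusted p = 2.507e-06). Neuropeptide-like genes (nlp) had 33 of 54 higher and 2 lower (adjusted p = 0.0001331), transthyretin-related genes (ttr) 29 of 48 higher (adjusted p = 0.0005631) and ubiquitin-conjugating enzymes (ubc) 14 of 19 higher (adjusted p = 0.003961). By the same test the prefix unc had 38 of 75 lower and 13 higher (adjusted p = 0.004117). The prefix slc had 18 of 31 lower and 5 higher (0.02722), and rab 12 of 18 higher and 1 lower (0.03256). No other family had an adjusted p under 0.05. The test treats genes as independent. How far members of these families vary together was not estimated, so these p-values may be too small and serve only to describe the counts. On chromosome X 780 of 2096 tested genes (37.21%) were lower at 5 days in water, against 26.05% to 30.37% on the autosomes.

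Of the tests below, those on the 1-day correlation and on the RPKM divisors were chosen only after the result was seen. At 5 days, libraries with neighbouring numbers deviated from their group means together, with a correlation of 0.5903 (95% interval 0.5355 to 0.6428 from blocks of 50 neighbouring genes) across 5081 genes over a mean log2 CPM of 5, and 0.1793 across all genes. A term for it called 465 genes, including T10D4.6 and ugt-64, higher in libraries 23 and 24 by 1.68 and 1.56 on the log2 scale, and pgp-1 and lipl-5, with log2 differences of -1.13 and -0.59. At 1 day the correlation was -0.1271 (interval -0.1752 to -0.08662) and the term called 0 genes. The 1-day neighbours thus did not deviate together, whereas handling shared by neighbouring numbers at both times predicted that they would. The intervals measure the spread over genes and not over libraries. Each age holds 1 pair of deviations, and pairing its libraries crosswise only turns the sign, so such handling is not excluded. Removing trends on exon length and expression left 0.6083 at 5 days, which argues against gene length bias. A culture or preparation day shared only at 5 days stays open as a candidate explanation, and no biological explanation was tested.

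For arsenite averaged over both times, 34 of the 35 splits of the 8 libraries into 4 against 4 could be fitted with time as a term. The real split, 1 of these 34, gave 0 genes, so every split gave at least as many whatever the data, and the count of splits says nothing about chance. The highest other split gave 53 genes and kept libraries 23 and 24 on one side.

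In the RPKM table, the ratio of the divisors followed the row number modulo 12 in at least 99.96% of rows for 21 of the 28 pairs of libraries, with ratios from 0.7902 to 1.266, and was 1 in at least 99.98% for the other 7, where it does not vary with the row number. Ratios of library totals spanned 0.7906 to 1.265. Library totals recycled along the rows of the table are a candidate cause, found and tested on the same values.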
